A study of Nothobranchius furzeri with 12 samples.

How the data were processed

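RNA was sequenced from brain and skin of the turquoise killifish Nothobranchius furzeri, a short-lived annual fish used in research on ageing. Per the labels of the samples, the fish belonged to the strain MZM-0410, which the design text of the series writes as MZM-0401. They had an age of 39 weeks, and gave 6 brain and 6 skin libraries, 1 per fish and tissue. Total RNA was made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Each library carried a fish number in the labels. The numbers 6, 8, 38, 41 and 46 occurred in both tissues, 24 in brain only and 12 in skin only. Libraries are named here by their labelled tissue and fish number, so that "the library labelled skin of fish 6" says what the label states and no more.

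The authors deposited 1 table with a read count and an RPKM value (reads scaled to gene length and to the library's total) for each of 23546 gene identifiers in each library. CASAVA 1.8.4, TopHat2 2.0.6 and featureCounts 1.4.3-p1 are named in the submitters' processing notes, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies and overlapping genes may share reads and their values are uncertain to that extent. The deposited counts were whole numbers with a different total in each library. The deposited RPKM values were checked against the counts. In 23212 genes with a count, the count, the RPKM and the library's total gave 1 gene length in every library within a relative tolerance of 0.001, so the authors' RPKM was scaled to the sum of gene counts. The other 334 genes had no count in any library. No row without a gene identifier was found, and all 12 libraries had both kinds of column.

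The identifiers were not paired with gene names in the file. Of the 23546 identifiers, 0 matched the identifiers, locus tags, synonyms or accessions of the 38438 genes in a RefSeq gene table of the assembly NfurGRZ-RIMD1. Gene names, functions and positions are therefore not given, and the 34 lists of marker and pathway genes fixed before the data were examined could not be applied. Their counts and set tests were not run. The rule for named genes, also fixed before the data were examined, took genes past the threshold that had a symbol, a mean of at least 100 CPM (counts scaled to library size) in the higher tissue and every library of that tissue above every library of the other, ranked by log2 fold change. The condition on a symbol could not be applied, and the identifiers of the first 2 genes in each direction are printed. The parts of the rule that named members of lists could not be used, and the most abundant genes are described without their identifiers.

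Counts were compared between tissues with edgeR 4.0.16 under R 4.3.3, with trimmed mean of M-values (TMM) factors, its default filter on low counts by tissue, robust quasi-likelihood fits and Benjamini-Hochberg adjusted p-values. Calls were made at a false discovery rate (FDR) of 0.05, and a separate test on the same fit asked for a change beyond 2-fold. All 12 libraries entered the fit under their labelled tissue. The design was fixed before the data were examined, with fish number as a block in an alternative. Standard errors of log2 fold changes were derived from the estimate and its test statistic. On simulated counts with the spread of the brain libraries, 99% of the genes changed 2-fold were recovered, and 100% of those changed 4-fold. With the spread of the 5 skin libraries other than that labelled skin of fish 6, these shares were 9% and 79%, and with the spread of the fit as labelled 2% and 40%. Each simulation changed 200 genes of 18299.

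The share of reads in the 10 most abundant genes, the number of detected genes and the spread between libraries were compared by exact two-sided permutation tests. These tests divided the libraries freely between the tissues, without regard to the fish numbers that the tissues share. Their p-values therefore take no account of the pairing. The spread of a library was the median, over genes with a mean of at least 10 CPM in both tissues, of the absolute deviation of its log2 CPM from the mean of the other libraries of its tissue. Genes for the spread and for the pairing of tissues were chosen, and counts scaled, over all 12 libraries, also where a library was left out. Detected genes were counted at an RPKM of at least 1 and, at equal depth, as genes with at least 10 reads after each library had been thinned to 9000000 reads. Genes enriched in a tissue were those with a median of at least 10 CPM in it and a median at least 20-fold lower in the other. For the levels given per library, these sets were chosen without the library being measured. Pairs of libraries were compared by a dispersion index, the mean over genes of the chi-square statistic of their counts. This index is 1 for sampling noise alone if reads are independent. Its 95% intervals came from 2000 bootstrap draws over genes. They treat genes as independent and do not cover variation between libraries. Over genes with at least 20 reads, no pair of libraries of one tissue lay within the sampling noise of independent reads. The lowest index was 6.21, for the brains of fish 8 and 24. All libraries were therefore counted separately.

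Pairing of the tissues was taken from the fish numbers in the labels. It was checked by the correlation, across genes, of the deviations of a fish's brain and skin from the tissue means. As labelled, the correlations of the 5 shared numbers ran from -0.302 to 0.119. Without fish 6, the 4 correlations ran from 0.148 to 0.283. A simulation of 4 fish with a shared effect put the true pairing first in 50 of 50 draws, over 2000 genes. The simulated genes were independent and the effect was set, so this checks the computation and not its power on these data.

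The total count was 9100419 to 27094192 reads per library. Reads without molecular identifiers are not independent molecules, so sampling noise alone need not give a dispersion index of 1. Alternatives were the block of fish number, other normalization factors, other filters, DESeq2 1.42.0, limma 3.58.1 on the deposited RPKM with pseudocounts of 1 and 0.1, the most abundant genes left out, and each library left out in turn. Further alternatives without the libraries labelled skin of fish 6 and 41 were chosen after seeing the data. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.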

Results

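Brain and skin of the killifish strain were each sampled in 6 fish at 1 age, 39 weeks, so the comparison the design implies is between the tissues, with the fish as replicates. Brain libraries held 20.7 ± 1.86 M reads in genes (SD, n = 6) and skin libraries 19.4 ± 6.51 M (SD, n = 6). The shallowest was skin of fish 46, with 9100419 reads, and the deepest skin of fish 41, with 27094192.

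The first question was how the libraries relate to their labels. Across the genes, the rank correlation (Spearman's rho) between brain libraries was 0.988 to 0.996. Among skin libraries other than that of fish 6 it was 0.901 to 0.978, and between those skin libraries and brain 0.578 to 0.717. The library labelled skin of fish 6 stood apart from its label. Its correlation with the 6 brain libraries was 0.973 to 0.978 and with the other skin libraries 0.646 to 0.756. These correlations are across genes, which are not independent replicates.

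**Figure D1:**
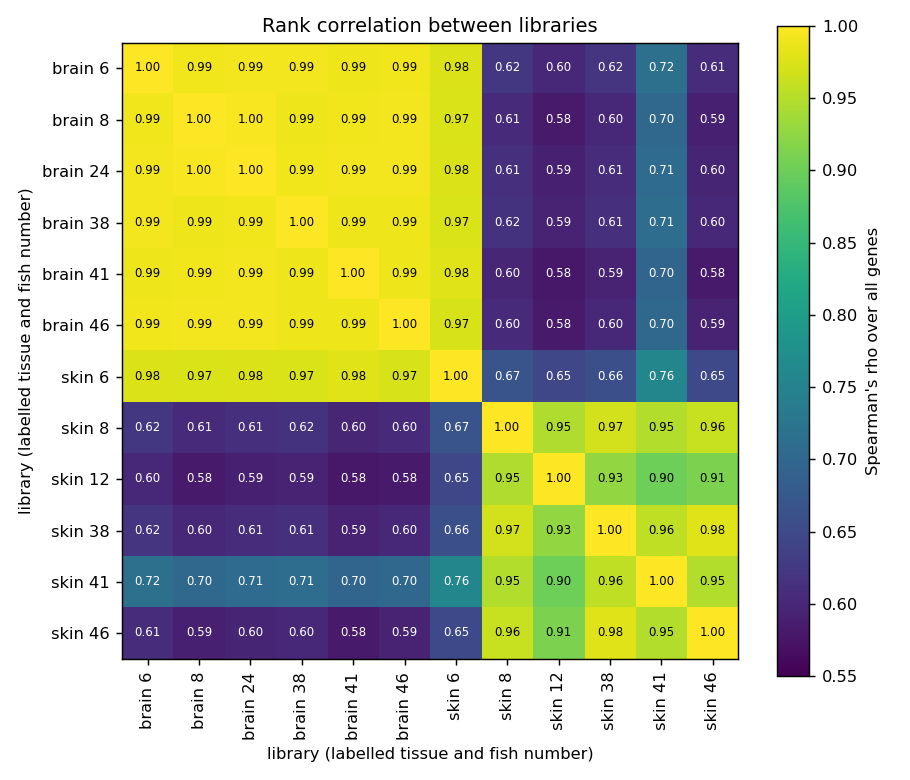
Spearman's rank correlation over all genes for each pair of the 12 libraries, named by labelled tissue and fish number, with the value in each cell and on the colour scale. The library labelled skin of fish 6 correlates at 0.973 to 0.978 with the brain libraries and at 0.646 to 0.756 with the other skin libraries.

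Genes enriched in a tissue gave the same picture per library. In the library labelled skin of fish 6, the 2174 brain-enriched genes had a median of 93.2% of their brain level (interquartile range 86.7 to 99.5%), and the 540 skin-enriched genes 8.81% of their skin level (3.84 to 14.6%). In the 6 brain libraries, the median level of skin-enriched genes was 0.894 to 1.42%. In 4 of the other skin libraries, brain-enriched genes were at 0.375 to 0.780% of the brain level, and in skin of fish 41 at 2.69%. For the library labelled skin of fish 6, set against each brain library over 2174 brain-enriched genes, the dispersion index was 2.88 (95% interval 2.70 to 3.05) for the brain of fish 41, 22.6 (15.0 to 32.7) for fish 24 and 37.3 to 50.9 for the others, with 45.6 for the brain of fish 6. This index grows with depth. With each library thinned to 9000000 reads it was 1.92 for the brain of fish 41 and 10.7 to 23.4 for the other brains. The gap was smaller over all genes with at least 20 reads, without thinning. There the index was 23.7 for the brain of fish 41, 29.3 for fish 24 and 33.9 to 36.2 for the others. Pairs of brain libraries had 6.21 to 22.4 over such genes. The median over genes, in place of the mean, kept the order with a smaller gap. Over brain-enriched genes it was 1.32 for the brain of fish 41 and 3.54 to 6.02 for the others. Over genes with at least 20 reads it was 2.64 and 3.05 to 3.91.

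**Figure D2:**
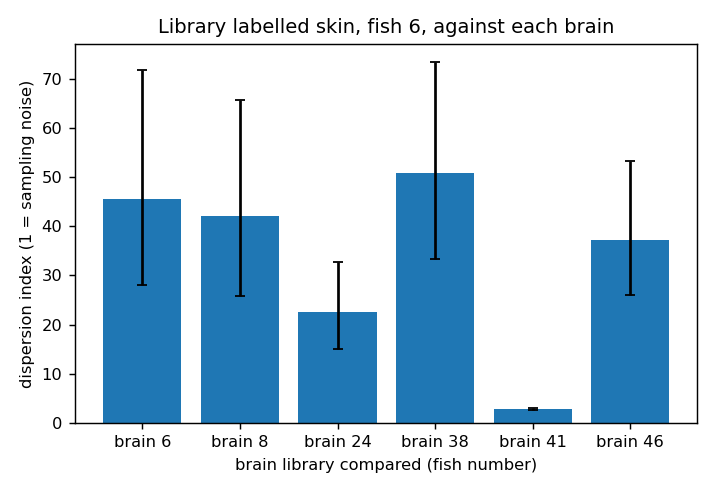
Dispersion index of the library labelled skin of fish 6 against each of the 6 brain libraries over 2174 brain-enriched genes. A value of 1 stands for the sampling noise of independent reads alone. Bars are means over genes and error bars 95% bootstrap intervals. The lowest value, 2.88, is for the brain of fish 41.

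The library labelled skin of fish 6 was kept in its labelled group, as the design had fixed, and the main results below are given with and without it.

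**Figure D3:**
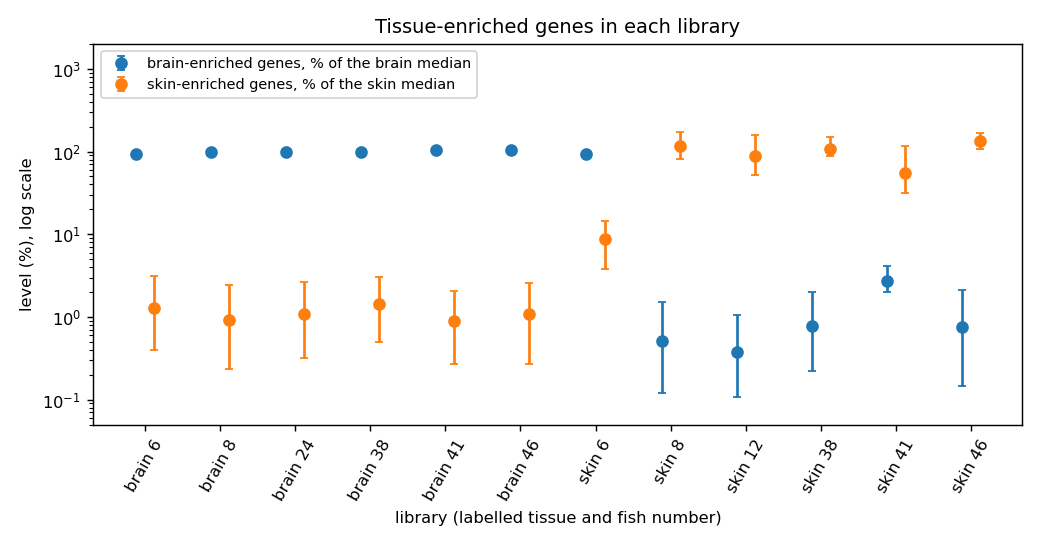
Median level of brain-enriched and skin-enriched genes in each library, as a percentage of the median in the tissue they are enriched in, on a log scale. Points are medians over genes and bars the interquartile range. The library labelled skin of fish 6 is at 93.2% for brain-enriched and 8.81% for skin-enriched genes.

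Many genes differed between brain and skin. As labelled, 11059 of 19797 genes tested passed an FDR of 0.05 (edgeR quasi-likelihood test, 6 against 6 libraries), 4754 of them higher in brain and 6305 higher in skin. A change beyond 2-fold was called for 3483 genes, 186 higher in brain and 3297 higher in skin. With the library labelled skin of fish 6 left out, 15376 genes passed, 7971 higher in brain and 7405 higher in skin. The 2-fold test then called 10220 genes, 5470 higher in brain and 4750 in skin. That single library thus changed the number past 2-fold by more than 1.5 times, and mainly among genes higher in brain. The smaller set was nearly contained in the larger, with 4752 of the 4754 brain-higher and 6304 of the 6305 skin-higher calls shared.

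Without that library, the genes past FDR 0.05 with a fitted change above 10-fold numbered 2841 higher in brain and 1803 higher in skin. As labelled they numbered 35 and 1446. With fish number as a block over the 12 libraries, 10610 genes passed FDR 0.05, 5808 higher in brain and 4802 higher in skin, so the majority direction of the fit as labelled was reversed. Of the calls as labelled, 3903 of the 4754 brain-higher and 4718 of the 6305 skin-higher ones were shared with it. The 2-fold test with the block called 457 genes, 7 higher in brain and 450 higher in skin. In that same fit, 2060 genes higher in brain and 1213 higher in skin passed FDR 0.05 with a fitted change above 10-fold. With the block and without the library labelled skin of fish 6, 15016 genes passed FDR 0.05, 7979 higher in brain and 7037 in skin, and the 2-fold test called 9925, 5354 higher in brain and 4571 in skin.

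The balance of directions was not stable across settings. Of the calls past FDR 0.05, 43.0% were higher in brain in the fit as labelled, 54.7% with the block, 51.8% without the library labelled skin of fish 6, and 73.3% with library size only in place of TMM factors. With that library left out and library size only, the share was 77.2%. On the deposited RPKM of the 12 libraries, limma with a pseudocount of 1 gave 78.6%. That fit differs from the edgeR fit in scaling, test, filter and pseudocount together, so its share cannot be assigned to one of them. The 2-fold split was reversed there, with 3234 genes higher in brain and 818 higher in skin at a pseudocount of 1, and 5630 and 1440 at a pseudocount of 0.1. Without the library labelled skin of fish 6, limma with a pseudocount of 1 called 7256 and 1511. The median log2 fold change (brain minus skin) over all genes was 0.07 with TMM factors and 0.98 with library size only, so directions are relative to a reference that scaling shifts by that much.

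**Figure D4:**
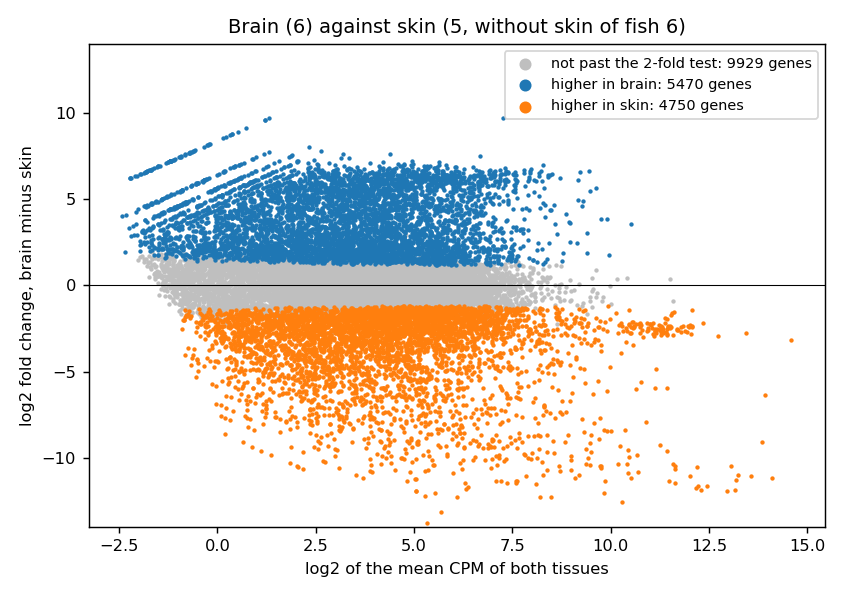
Log2 fold change (brain minus skin) against the log2 mean CPM of both tissues, 1 point per gene, for 6 brain and 5 skin libraries without the library labelled skin of fish 6. Blue points are the 5470 genes higher in brain and orange points the 4750 genes higher in skin past the 2-fold test.

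The fixed rule took Nfu_g_1_007783 and Nfu_g_1_014314 as the first 2 genes higher in brain. Nfu_g_1_007783 was at 203 ± 103 TMM-scaled CPM in brain (SD, n = 6) and 6.90 ± 14.3 in skin as labelled (SD, n = 6), with a log2 fold change of 4.85 (SE 1.25, edgeR adjusted p = 0.00862). It was at 36.1 in the library labelled skin of fish 6 and at 39.8 in the brain of fish 41, the lowest brain. When that library was left out, the skin mean was 1.06 ± 0.897 (SD, n = 5) and the log2 fold change 7.50 (SE 0.77, edgeR adjusted p = 2.23e-06). Nfu_g_1_014314 was at 1613 ± 525 in brain (SD, n = 6) and 229 ± 309 in skin as labelled (SD, n = 6), with a log2 fold change of 2.79 (SE 0.80, edgeR adjusted p = 0.0138). Leaving out the library labelled skin of fish 6 gave a skin mean of 108 ± 98.6 (SD, n = 5) and a log2 fold change of 3.83 (SE 0.64, edgeR adjusted p = 0.000137).

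Nfu_g_1_022203 and Nfu_g_1_010150 were the first 2 genes higher in skin. Nfu_g_1_022203 was at 2108 ± 1605 TMM-scaled CPM in skin as labelled (SD, n = 6) and 0.427 ± 0.233 in brain (SD, n = 6), with a log2 fold change (brain minus skin) of -12.32 (SE 1.11, edgeR adjusted p = 4.65e-05). In the library labelled skin of fish 6 it was at 57.9. Nfu_g_1_010150 was at 503 ± 395 in skin as labelled (SD, n = 6) and 0.119 ± 0.101 in brain (SD, n = 6), where its count was 0 to 9 reads per library, with a log2 fold change of -12.04 (SE 1.04, edgeR adjusted p = 4.65e-05). In the library labelled skin of fish 6 it was at 57.8. As labelled, 134 genes higher in brain and 699 higher in skin met the other conditions of the rule, and without that library 876 and 1255 did. In the fit without that library the same rule still took Nfu_g_1_007783 and Nfu_g_1_022203 among its first 2 in each direction, but not Nfu_g_1_014314 or Nfu_g_1_010150.

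Reads were concentrated in fewer genes in skin than in brain. The 10 most abundant genes took 14.7 ± 5.60% of the reads in skin as labelled (SD, n = 6). In brain they took 3.70 ± 0.134% (SD, n = 6; exact two-sided permutation test, p = 0.00216). That p-value is the smallest that free division of the libraries allows, without regard to shared fish numbers. Without the library labelled skin of fish 6 the skin share was 16.8 ± 2.11% (SD, n = 5). The number of genes that made up 50% of the reads was 1287 to 1355 in brain, 106 to 147 in 5 skin libraries and 1288 in the library labelled skin of fish 6. The most abundant gene was the same in both tissues, at 7282 ± 614 CPM in brain (SD, n = 6) and 27966 ± 5193 in skin without that library (SD, n = 5). The next most abundant skin gene was at 22369 ± 8723 CPM (SD, n = 5) in skin and 21.9 ± 8.83 in brain (SD, n = 6).

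**Figure D5:**
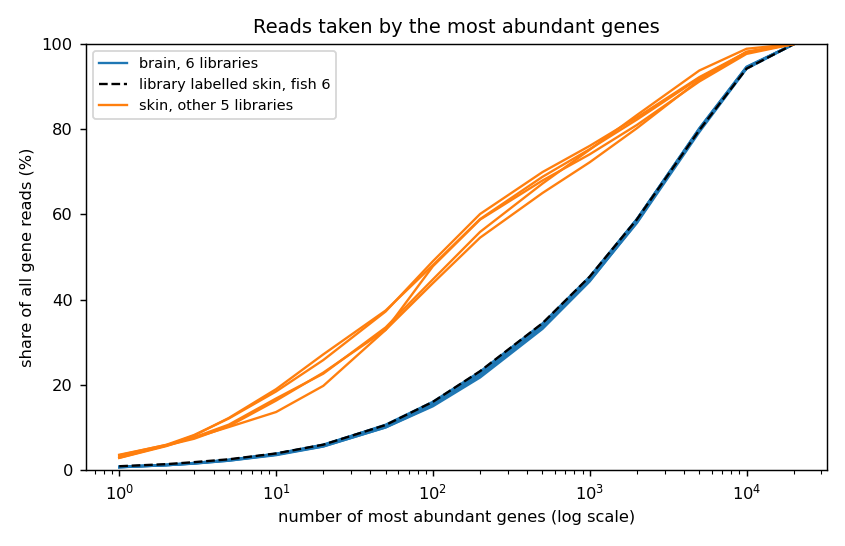
Share of all gene reads in the most abundant genes of each library, against the number of genes on a log scale, 1 line per library. The 5 skin lines lie above the 6 brain lines, and the dashed line of the library labelled skin of fish 6 follows the brain lines.

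Brain had more genes detected. At an RPKM of at least 1, 17099 ± 146 genes were detected in brain (SD, n = 6) and 14072 ± 1868 in skin as labelled (SD, n = 6; exact two-sided permutation test, p = 0.0152). Without the library labelled skin of fish 6 the skin number was 13406 ± 1017 (SD, n = 5; exact two-sided permutation test, p = 0.00216). At an equal depth of 9000000 reads, genes with at least 10 reads numbered 18123 ± 143 in brain (SD, n = 6), 15849 ± 1507 in skin as labelled (SD, n = 6) and 15335 ± 927 in skin without that library (SD, n = 5), so the difference was present at a matched total. The 100 most abundant genes took a mean of 46.7% of the reads in those 5 skins and 15.6% in brain. Fewer reads were thus left for the other skin genes, and how much of the difference this makes was not tested.

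Skin libraries differed from each other more than brain libraries did. With 1 library per fish and tissue, differences between fish were not separated from those between samples of a tissue. Over 8517 genes, the median absolute log2 deviation of a library from the others of its tissue was 0.51 ± 0.26 in skin as labelled (SD, n = 6). In brain it was 0.08 ± 0.01 (SD, n = 6; exact two-sided permutation test, p = 0.00216). That p-value is again the smallest that free division of the libraries allows, without regard to shared fish numbers. Without the library labelled skin of fish 6 the skin value was 0.41 ± 0.19 (SD, n = 5; exact two-sided permutation test, p = 0.00216). The lowest skin value was then 0.27 and the highest brain value 0.10. Each value was computed from the other libraries of its tissue. The values are thus not independent, and both p-values are only a description. Skin of fish 12 had the largest deviation of the remaining skin libraries, at 0.74, against 0.27 to 0.43 in the other 4. The coefficient of biological variation estimated by edgeR was 15.0% for brain, 88.3% for skin as labelled and 50.6% for the 5 skin libraries.

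The last comparison asked whether brain and skin with the same fish number deviate from their tissue in the same genes. As labelled, the mean correlation over the 5 shared numbers was -0.00779, and 65 of the 120 possible pairings gave a mean as large (exact one-sided permutation test, p = 0.542). With fish 6 left out, a choice made after seeing the data, the mean correlation was 0.184 over the 4 remaining fish. No other of the 24 pairings was as large (exact one-sided permutation test, p = 0.0417, the smallest possible), and each of the 4 skins correlated best with the brain of its own number. The highest mean of another pairing was 0.106. Among these skins, that of fish 41 held brain-enriched genes at 2.69% of the brain level. This signal could raise its correlation with the brain of fish 41, which was 0.148. The genes were still chosen with the library labelled skin of fish 6 included, which lets in genes low in the other skins. How far the pairing rests on either was not tested, and the p-value needs all 4 pairs.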

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

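The tests on the library labelled skin of fish 6, the tests on skin of fish 41 and the counts of other splits were chosen or given their bounds after the values were seen.

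Of the 32 groups of 6 library values examined, 8 held 1 library far from the other 5, and chance alone gives about 1 in 20. All 8 were the library labelled skin of fish 6. The 8 overlap in what they measure and are not independent results. Its share of reads in the 10 most abundant genes was 3.91%, against 13.6 to 19.0% in the other skin libraries. Its number of genes making up 50% of the reads was 1288, against 106 to 147. Its brain-enriched genes were at 93.2% of the brain level, against 0.375 to 2.69%, and took 22.5% of its reads, against 0.239 to 0.774%. Its median rank correlation was 0.660 with the other skin libraries, which had 0.912 to 0.958 with theirs, and 0.975 with the brain libraries, against 0.586 to 0.704. It had 36.1 TMM-scaled CPM of Nfu_g_1_007783, against 0.190 to 2.39, and 833 of Nfu_g_1_014314, against 16.0 to 265.

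The brain-like content of this library was weighed against 3 technical explanations, and no biological one was tested, since the design names none for 1 library. An exchange with a brain library of the series is argued against by the brain libraries, in which the highest median level of skin-enriched genes was 1.42%. Brain tissue of fish 6 itself is argued against by the dispersion index, which was 45.6 (95% interval 28.0 to 71.9) against the brain of fish 6 and 2.88 (2.70 to 3.05) against that of fish 41. With each library thinned to 9000000 reads these were 21.1 and 1.92. Over all genes with at least 20 reads, without thinning, they were 33.9 and 23.7, a smaller gap in the same direction. A candidate explanation is material of the fish 41 brain with a part of skin, whose skin-enriched genes were at 8.81% of the skin level (interquartile range 3.84 to 14.6%), above every brain library, while the size of the skin part and the step at which mixing or mislabelling may have happened stay open.

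Skin of fish 41 held a small brain-like signal, at a median of 1.96% of the brain level (interquartile range 1.61 to 2.33%) over 413 genes of at least 20 CPM in brain and at most 0.3 CPM in each of the skins of fish 8, 12, 38 and 46. For each of those 4 skins, a set with the bound of 0.3 CPM in only the rest of them gave 0.0737 to 0.156%. The brain-enriched genes that all these sets drew on were chosen with the measured skin included. These levels are scaled to depth. Material of the fish 41 brain is a candidate explanation, since the index was lowest against that brain, 1.88, and the smallest difference to another brain was 0.283 (95% interval 0.113 to 0.458), for fish 24, and 0.359 (0.173 to 0.554) with the brains thinned to 9000000 reads each. These intervals treat genes as independent and do not cover variation between libraries. The index against the library labelled skin of fish 6 was 1.99, so that library stays open as a source. A source in the skin itself was not tested. Skin of fish 41 also had its skin-enriched genes at a median of 55.2% of the skin level (interquartile range 31.6 to 117%). In the skins of fish 8, 12, 38 and 46 the medians were 89.1 to 133%. The cause of this was not tested.

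Counts over other splits of the libraries were set beside those of brain against skin. A split that mixes the tissues turns their difference into spread within groups, so a low count was fixed beforehand. The drawn splits, nearly all mixed, therefore cannot exclude chance division. Among 100 splits of the 12 libraries, drawn from 462, 1 gave as many genes past FDR 0.05 as labelled, the real one with 11059, and the highest other gave 0. For the 2-fold test it was again 1, with 3483 against 0. Without the library labelled skin of fish 6, 1 of 100 splits gave as many, 15376 genes against a highest other of 7946, and for the 2-fold test 10220 against 2984. That other split set the brain of fish 8 with the 5 skins against the other 5 brains, which points to the tissue structure itself. The drawn splits that parted as many fish pairs, 8 and 6 in the 2 sets of libraries, gave 0 genes. Exchanging the library labelled skin of fish 6 with a brain library, run apart from the drawn splits, gave 9659 to 10328 genes past FDR 0.05. These exchanges are among the 462 possible splits but were not drawn.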

How the results depend on the processing

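The tissue differences in the most abundant genes' share and in the spread between libraries kept their direction. They stayed past the threshold of the permutation tests in all 14 and 17 alternatives run. When 1 library was left out, the differences (skin minus brain) were 10.1 to 13.1 percentage points and 0.33 to 0.51. The 4 named genes kept their direction and call in all 32 alternatives each, with log2 fold changes over all of them of 4.59 to 8.69 for Nfu_g_1_007783, 2.54 to 5.52 for Nfu_g_1_014314, -12.58 to -9.11 for Nfu_g_1_022203 and -12.52 to -8.84 for Nfu_g_1_010150. These genes were chosen from the same data as called and without overlap between the tissues, so their stability is no separate support. The count past FDR 0.05 was 8615 to 15376 when 1 library was left out, and the count past 2-fold 3125 to 10220. The highest of both came without the library labelled skin of fish 6. With any other library left out they were at most 11218 and 3367.

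With the replicate block, pairing libraries by fish number, the 2-fold count was 457 over 12 libraries, 464 over the 5 shared fish and 9925 without the library labelled skin of fish 6. The block ended no call of a named gene. The 2-fold count was 1661 with library size only and 7070 with limma and a pseudocount of 0.1. The cause was not tested. Alternatives without the library labelled skin of fish 6 were chosen after seeing the data, apart from leaving it out alone. Their 2-fold counts were 10300 with RLE factors, 10197 with upper quartile factors, 12218 with library size only, 9115 with DESeq2, 8767 with limma, 10209 without the most abundant genes and 10605 without skin of fish 41 too. With limma, 17955 genes passed FDR 0.05. The mean correlation of paired tissues without fish 6, also chosen after seeing the data, was 0.184, and 0.173 and 0.217 at minimums of 1 and 100 CPM, each with an exact permutation p of 0.0417. Genes for these were still chosen over all 12 libraries. The gene list alternatives were not run, since no identifier was paired with a name. In simulated counts with the spread of the fit as labelled, 2% of 2-fold changes were recovered, and 9% with that of the 5 other skins. Only 200 of 18299 genes were changed there, while 11059 of 19797 were called in the fit as labelled. The FDR cut-off depends on the share of changed genes, so these values do not give the recovery in the data. An uncalled gene is still not shown to be unchanged.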

Other observations

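A set of genes was higher in 3 brains than in the other 3. Of 98 genes with a maximum of at least 3 CPM and a range of at least 10-fold over the 6 brains, 13 were at least 3-fold higher in every one of the brains of fish 6, 38 and 46 than in any of the brains of fish 8, 24 and 41. The other divisions of the brains 3 against 3 held 0 to 4 such genes. The fish were divided by these values and not by a label, so no test of the division is given. Together the 13 genes took 0.195% of the reads in the brain of fish 6, 0.200% in fish 38 and 0.0995% in fish 46. They took 0.000600% in fish 8, 0.000513% in fish 24 and 0.00114% in fish 41. The member with the largest fold was at 1133, 749 and 694 CPM in the first 3 brains and at most 4.78 CPM in the others. In the library labelled skin of fish 6 the 13 genes took 0.00173% of the reads, and in the 5 other skins 0.00532 to 0.00922%. In all of those 5 skins, 9 of the 13 genes were below 1 CPM, while 1 member was at 49.5 to 74.6 CPM, above its level in each brain. Without gene names, what these genes are was not established.

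Skins differed unequally from each other. Over genes with at least 20 reads, the dispersion index of the skins of fish 38 and 46 was 18.9, while the other pairs of the 5 skins had 91.5 to 403. The brain pairs had 6.21 to 22.4. The index grows with depth, and the skins of fish 38 and 46 were the shallowest libraries. With each library thinned to 9000000 reads, the index was 15.9 for this pair, 60.5 to 166 for the other skin pairs and 3.31 to 10.8 for the brain pairs.

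Some genes varied alike in brain and skin over the fish numbers compared. Over fish 8, 38, 41 and 46, 66 genes had a correlation above 0.9 between brain and skin and a range of at least 1.5 on the log2 scale in each tissue. Of the other pairings of these libraries, out of 24 in all, the highest gave 43 genes and the median was 8. The brain-like signal of 1.96% in skin of fish 41 could add to the count of 66, which was not tested. In these 66 genes, the library labelled skin of fish 6 had a median absolute log2 difference of 0.25 from the brain of fish 41 and 0.80 to 1.28 from the other brains.

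Gene lengths were compared between the sets of calls. Without the library labelled skin of fish 6, the median length of genes past the 2-fold test was 2542 bp for those higher in brain and 2462 bp for those higher in skin. As labelled the order was the other way, 1674 bp for the 186 genes higher in brain and 2571 bp for the 3297 higher in skin. Without that library, in 5 classes of about equal number by length, the median log2 fold change (brain minus skin) was 0.05, 0.06, -0.16, -0.04 and 0.33, from the shortest to the longest.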
